A study of Mus musculus with 28 samples.

How the data were processed

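Messenger RNA was sequenced from 16 mouse livers and from 12 cultures of bone marrow-derived macrophages. Per the labels, the livers came from male mice fed a methionine- and choline-deficient diet for 4 weeks from 8 weeks of age, a diet that brings on steatohepatitis. They fall into 4 groups of 4: Lyz2-Cre controls, mice whose Lyz2-expressing (myeloid) cells lack NFATc3 (NFATc3-MKO), mice whose myeloid cells lack ASK1 (ASK1-MKO), and mice whose myeloid cells lack both (MDKO). NFATc3 is a transcription factor activated by calcineurin, and ASK1, encoded by Map3k5, is a stress-activated kinase. The macrophages were grown for 7 days in medium with 30% L929-conditioned medium, a source of macrophage colony-stimulating factor. They came from mice with a knock-in of NFATc3 (NFATc3-MKI) or of ASK1 (ASK1-MKI), with 3 cultures each and a separate set of 3 controls for each knock-in.

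Per the labels, RNA was taken up in TRIzol, poly-A RNA was made into dUTP strand-specific libraries, and reads were aligned with HISAT2 to mm10. The program that counted reads, its annotation and its strand setting are not given in the sources used here. The deposited liver table holds expected counts (estimated counts) for 17752 gene symbols, and 85.42% of its values were whole, that is, equal to their rounded value as written. The deposited tables for NFATc3-MKI and for ASK1-MKI hold raw counts for 56748 and 21959 Ensembl gene identifiers, all of them whole, of which 32076 and 6420 were 0 in every library. No normalisation by the authors was found in any of the 3 tables. Of these features, 16815, 52073 and 21851 were matched to a gene name in the annotation of mm10, which also gave the positions printed for the targeted genes.

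Total counts per library ran from 20601168 to 30834547 in 15 livers and were 8912117 in MDKO replicate 3. They ran from 7693464 to 9398163 in the cultures for NFATc3-MKI and from 16051951 to 18728508 in those for ASK1-MKI. Limits for genes at a count of 0 used a floor of 3 counts over the group's libraries and cover counting error only.

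Each table was fitted separately, with the liver values rounded to whole numbers and all 16 livers in one fit, so that the 4 groups shared an estimate of the spread. Genes were kept by edgeR's filterByExpr (version 4.0.16 in R 4.3.3), which left 13309, 13363 and 11380 genes. Libraries were scaled by the trimmed mean of M values, with factors of 0.875 to 1.203, 0.978 to 1.016 and 0.99 to 1.012. The common biological coefficient of variation was 0.208, 0.089 and 0.021. Differences were tested by edgeR's robust quasi-likelihood F test with the Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called changed at an adjusted p under 0.05. Every log2 fold change is the first group named minus the second. Its standard error (SE) is its size divided by the square root of F. Levels are in CPM, edgeR's counts scaled to the library size, given as mean ± SD. The interaction was MDKO minus NFATc3-MKO, less ASK1-MKO minus Lyz2-Cre. Nfatc3 and Map3k5 were also tested by a two-sided exact permutation test on log2 CPM with a prior count of 2. It has 70 assignments for 4 against 4 libraries and 20 for 3 against 3, so its smallest p is 0.0286 and 0.1.

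Before the data were examined, the comparisons, 27 gene lists and 17 lists of cell type markers, the rule for named genes and most alternatives were fixed. Lists with at least 4 measured members were tested with limma's camera (version 3.58.1) at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Per comparison the rule named Nfatc3 and Map3k5, and the 8 genes that rose most and the 8 that fell most (4 of each in comparisons with MDKO and in the interaction). These had to be past the threshold, at a mean of at least 1 CPM in the higher group, with groups that did not overlap. It also named up to 4 members with the smallest p of each called list and, from uncalled lists, the most abundant members. Clock genes and genes outside these rules are named as chosen after their values were seen.

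Alternatives were DESeq2's size factors, DESeq2's Wald test (version 1.42.0), limma's voom with quality weights, no filter, a mean of at least 1 CPM, an adjusted p under 0.1, an added 2-fold limit, the replicate number as a block, only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were a fit of MDKO and Lyz2-Cre livers alone with the block, removal of a per-library trend on GC content and length (a spline with 5 degrees of freedom), and autosomal genes only for ASK1-MKI. The 3 liver knockouts share their controls, so the correlation of their changes was set against 100 simulated data sets of unchanged groups sharing controls (10 for shared calls), and recomputed with the controls split.

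The labels give no pairing. Same-numbered libraries were checked for shared deviations from their group means in the 6 pairs of liver groups and in both culture tables. Only Lyz2-Cre and MDKO livers qualified: all 4 same-numbered pairs correlated above 0.1 across genes, from 0.24 to 0.53, and each library was most like the one with its own number. The mean of 0.38 was therefore the highest of the 24 ways to match them, with an exact one-sided p of 0.0417, the smallest possible. That p restates the likeness of same numbers and is not adjusted for the 6 pairs of groups examined. The other pairs of groups did not have all correlations above 0.1, and the block was used as an alternative throughout.

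The methods were tested on simulated data with the means and spreads of these tables. Genes changed 1.5-fold and 2-fold were recovered in 22% and 64.6% of cases in the liver design, with 4 unchanged genes called. In the NFATc3-MKI design 66% and 87% were recovered with 15 unchanged genes called, and in the ASK1-MKI design 89% and 98% with 17. Every library was used. Reads were not analysed here.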

Results

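RNA was sequenced from 16 livers of mice on a steatohepatitis-inducing diet and from 12 cultures of bone marrow-derived macrophages. The livers were labelled MDKO, ASK1-MKO, NFATc3-MKO and, as controls, Lyz2-Cre (n = 4 each), and the cultures NFATc3-MKI and ASK1-MKI, each with its own controls (n = 3 each). Total counts were 20601168 to 30834547 in 15 livers and 8912117 in MDKO replicate 3. They were 7693464 to 9398163 in the NFATc3-MKI set and 16051951 to 18728508 in the ASK1-MKI set.

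The targeted genes were examined first, to see whether the libraries carry the change their labels name. Nfatc3 (ENSMUSG00000031902, chromosome 8, 106058840 to 106130537 in mm10) stood at 28.31 ± 5.78 CPM in livers labelled NFATc3-MKO and 36.28 ± 3.94 in Lyz2-Cre livers (log2 change −0.36 ± 0.14 SE, edgeR adjusted p = 0.12, exact permutation p = 0.114). NFATc3-MKO replicate 3 stood at 19.6 CPM and the others of its group at 30.9 to 31.5. Among alternatives with no library left out, Nfatc3 passed only with voom (−0.31, limma adjusted p = 0.0419) and the GC and length correction (−0.32, edgeR adjusted p = 0.0313). Map3k5, the gene for ASK1 (ENSMUSG00000071369, chromosome 10, 19934472 to 20142753), was higher in livers labelled ASK1-MKO, at 46.26 ± 6.13 against 30.89 ± 2.21 CPM (log2 change 0.58 ± 0.15, edgeR adjusted p = 0.0262, exact permutation p = 0.0286, the smallest possible). That is against its label. The labels name a loss in myeloid cells only, however. Whole liver holds many other cells, so such a loss may leave these values little changed. The call was lost without ASK1-MKO replicate 2 (edgeR adjusted p = 0.0861), Lyz2-Cre replicate 3 (0.0887) or Lyz2-Cre replicate 4 (0.0645). In livers labelled MDKO neither gene fell past the threshold: Nfatc3 stood at 36.59 ± 4.61 CPM (log2 change 0.01) and Map3k5 at 30.56 ± 2.15 (−0.02, edgeR adjusted p = 1 for both).

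Neither knock-in culture held more RNA of its gene. Nfatc3 stood at 81.12 ± 8.04 CPM in cells labelled NFATc3-MKI and 97.44 ± 7.32 in their controls (log2 change −0.26 ± 0.10, edgeR adjusted p = 0.0371, exact permutation p = 0.1, the smallest possible). Map3k5 stood at 26.92 ± 0.35 CPM in cells labelled ASK1-MKI and 30.15 ± 0.175 in their controls (−0.16 ± 0.06, edgeR adjusted p = 0.0266, exact permutation p = 0.1). Both go against the labels, but whether an added copy would be counted as its gene was not tested. For Nfatc3 the call was lost with DESeq2 (adjusted p = 0.0523) and without control replicate 2 (0.157), control replicate 3 (0.0902), NFATc3-MKI replicate 1 (0.143) or NFATc3-MKI replicate 3 (0.166). For Map3k5 it was lost with DESeq2 (0.0827) and without ASK1-MKI replicate 1 (0.0639) or 3 (0.0676) or control replicate 1 (0.0552) or 3 (0.0639). Every direction given here therefore refers to libraries labelled with a genotype, not to a verified change in the targeted gene.

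**Figure D1:**
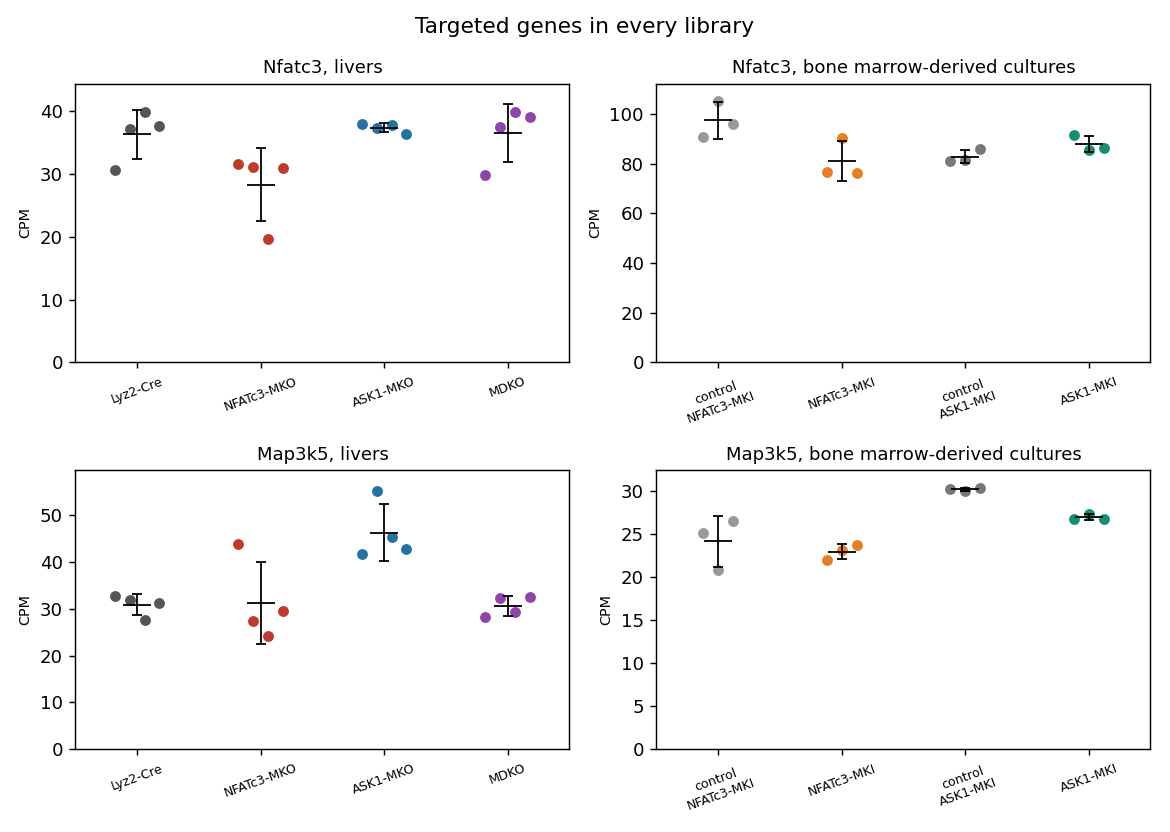
CPM of Nfatc3 (top) and Map3k5 (bottom) in each liver (left) and culture (right), on linear axes from 0. Points are libraries, bars the group mean ± SD (n = 4 for livers, n = 3 for cultures); Map3k5 has its highest liver mean, 46.26 CPM, in the livers labelled ASK1-MKO.

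The livers were compared across all genes. On the first principal component (27.4% of the variance), NFATc3-MKO replicates 2, 3 and 4 lay apart at scores of 54.8, 51.8 and 36.5, whereas NFATc3-MKO replicate 1 lay at −3.5. Lyz2-Cre replicate 2 lay at 16.3 and the other controls at −16.4 to −9.6. On the second (17.1%) the ASK1-MKO livers lay at 22.5 to 29.9, and the Lyz2-Cre and MDKO livers at −28.8 to −4.6. NFATc3-MKO replicates 1, 2, 3 and 4 lay there at 17.1, 2.8, 19.1 and 3.9.

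**Figure D2:**
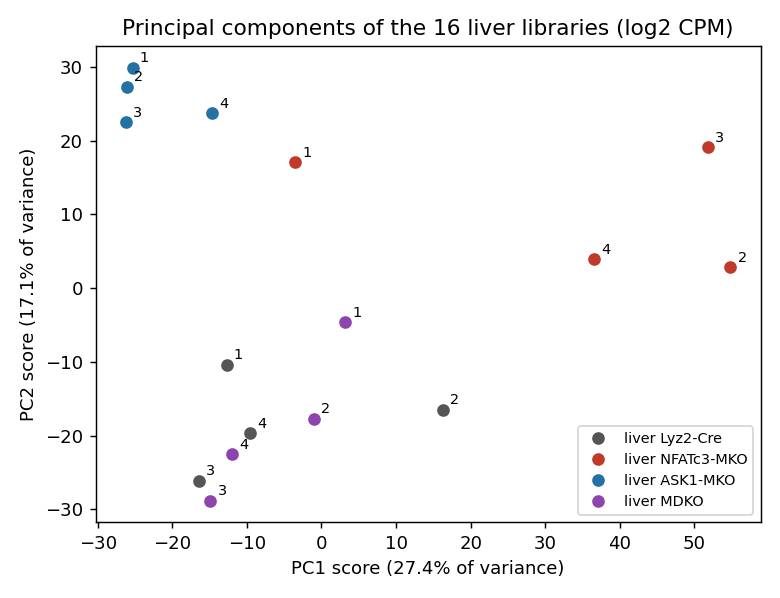
Scores of the 16 livers on the first and second principal components of log2 CPM, with replicate numbers beside the points. Lyz2-Cre and MDKO livers share the lower part of the plot, with second-component scores of −28.8 to −4.6.

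Livers labelled NFATc3-MKO were compared with Lyz2-Cre livers to find what loss of myeloid NFATc3 changes in the diseased liver. Matrix and scar genes and markers of lipid-associated macrophages, neutrophils and bile duct cells were called higher as lists, and genes of lipid synthesis and markers of Kupffer cells and hepatocytes lower, mostly with a minority of members past the threshold. None of these calls held with an estimated correlation in camera (adjusted p = 0.877 to 0.915). Among genes at a mean of at least 1 CPM whose groups did not overlap, taken by the rule for named genes, the sulfotransferase gene Sult2a3 rose most, from 2.29 ± 1.26 to 32.6 ± 6.72 CPM (log2 change 3.83 ± 0.35, edgeR adjusted p = 6.53e-05), followed by Sult2a2 (2.40 ± 0.47), whose close paralogs can share reads. Cyp17a1, a steroid-synthesis enzyme (−2.96 ± 0.34, edgeR adjusted p = 0.000533), and Slco1a1, an organic anion transporter (−2.94 ± 0.52, 0.00564, and −3.98 without NFATc3-MKO replicate 1), fell most by the same rule. In all, 502 genes rose and 622 fell of 13309 (1124 in total), with a change of at least 2-fold in 158 and 119.

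Of 30 fibrosis and extracellular matrix genes 6 rose and none fell, or 19 and none when adjusted over the list alone (camera adjusted p = 2.63e-05, adjusted p = 0.915 with an estimated correlation). Lox, which cross-links collagen, rose by 2.83 ± 0.63 (log2, edgeR adjusted p = 0.014), by 3.61 without Lyz2-Cre replicate 2 and by 2.10 without NFATc3-MKO replicate 2, and Tagln, a marker of activated stellate cells and myofibroblasts, by 1.25 ± 0.31 (0.0222). Of 18 lipogenesis genes 4 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 7.82e-05, adjusted p = 0.877 with an estimated correlation). The fatty acid desaturase gene Fads2 fell from 1577 ± 147 to 760 ± 151 CPM (−1.05 ± 0.17, edgeR adjusted p = 0.00321), with Fads1 at −0.84 ± 0.13 and Scd1, which makes oleate, at −1.78 ± 0.36 (0.00818). Of 22 genes of fatty acid oxidation none passed singly, also when adjusted over the list alone, but the list was lower (camera adjusted p = 0.00464, adjusted p = 0.941 with an estimated correlation). That call was lost without Lyz2-Cre replicate 1 (camera adjusted p = 0.0856). Of 15 bile acid genes 2 fell, Slco1a1 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (−1.27 ± 0.33, edgeR adjusted p = 0.0291). The count was the same adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.916 with an estimated correlation). The call was lost without Lyz2-Cre replicate 1 (camera adjusted p = 0.128) or NFATc3-MKO replicate 2 (0.164), 3 (0.169) or 4 (0.0613).

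Cell type markers moved with these groups. Of 10 Kupffer cell markers 3 fell (3 adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.877 with an estimated correlation), among them C6 (−0.91 ± 0.15) and the lectin gene Clec4f, at 38.02 ± 12.4 against 84.07 ± 21.4 CPM (−1.14 ± 0.30, edgeR adjusted p = 0.0305). Of 12 markers of monocyte-derived and lipid-associated macrophages 1 rose, and 10 did when adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.894 with an estimated correlation). It was Spp1, the osteopontin gene, at 265.9 ± 124 against 73.2 ± 29.3 CPM (1.86 ± 0.46, edgeR adjusted p = 0.0241). The groups overlapped: NFATc3-MKO replicate 1 stood at 85.2 CPM and the other 3 at 290.4 to 366, and Lyz2-Cre replicate 2 at 116. Neutrophil markers rose in 2 of 6 (4 adjusted over the list alone, camera adjusted p = 0.00601, adjusted p = 0.877 with an estimated correlation), namely S100a9 (2.45 ± 0.64) and S100a8 (2.21 ± 0.63). Without Lyz2-Cre replicate 2 these were 3.19 and 3.26, and without NFATc3-MKO replicate 2 they were 1.76 and 1.60, no longer past the threshold (edgeR adjusted p = 0.0879 and 0.118). Cholangiocyte markers rose in 4 of 8, and in 4 adjusted over the list alone (camera adjusted p = 0.00464, adjusted p = 0.877 with an estimated correlation), with Epcam at 1.93 ± 0.52. B and plasma cell markers rose in 2 of 7, Jchain (1.65 ± 0.32) and Igkc (1.83 ± 0.37), and in 3 adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.877 with an estimated correlation, camera adjusted p = 0.083 with the replicate block). That call was also lost without Lyz2-Cre replicate 1 (0.0936) or 3 (0.0891) or NFATc3-MKO replicate 2 (0.121), 3 (0.0771) or 4 (0.0686), each a camera adjusted p. Hepatocyte markers fell in 2 of 16 (3 adjusted over the list alone, camera adjusted p = 0.000879, adjusted p = 0.877 with an estimated correlation), including Hnf4a, a master regulator of hepatocyte identity (−0.55 ± 0.11, edgeR adjusted p = 0.00755). Liver endothelial markers fell in 2 of 11 (3 adjusted over the list alone, camera adjusted p = 0.00696, adjusted p = 0.894 with an estimated correlation), Clec4g (−0.68 ± 0.19) and Fcgr2b (−0.60 ± 0.18).

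The 16 inflammatory cytokine and chemokine genes had no member past the threshold (camera adjusted p = 0.215). The count of 1124 rests on few livers. It was 722, 268 and 377 without Lyz2-Cre replicates 1, 3 and 4, 602 without NFATc3-MKO replicate 3, and 218 with only the 2 groups in the fit. Exchanging NFATc3-MKO replicate 1 and Lyz2-Cre replicate 2 between the groups gave 1135 changed genes, so chance cannot be excluded for the count. Of 44 called genes that were followed, some chosen after their values were seen, 22 lost their call without at least 1 library. Without Lyz2-Cre replicate 3 the calls were lost of Lox, Tagln, Cyp7a1, Clec4f and Spp1 (edgeR adjusted p = 0.0622, 0.0844, 0.0861, 0.105 and 0.0946) and of S100a9, S100a8, Epcam, Clec4g and Fcgr2b (0.111, 0.129, 0.104, 0.124 and 0.127). Without Lyz2-Cre replicate 4 they were lost too (0.0536, 0.0609, 0.0792, 0.0639 and 0.0736, and 0.0921, 0.116, 0.0877, 0.0607 and 0.0947), and all but Lox also without further libraries. Sult2a3, Cyp17a1, Slco1a1, Fads1, Fads2, Scd1, C6 and Hnf4a kept theirs whichever single library was left out, but Hnf4a lost its call with only the 2 groups in the fit (edgeR adjusted p = 0.0594). The 2 groups did not overlap in 1704 genes (12.8%), against a chance share of 0.0286.

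**Figure D3:**
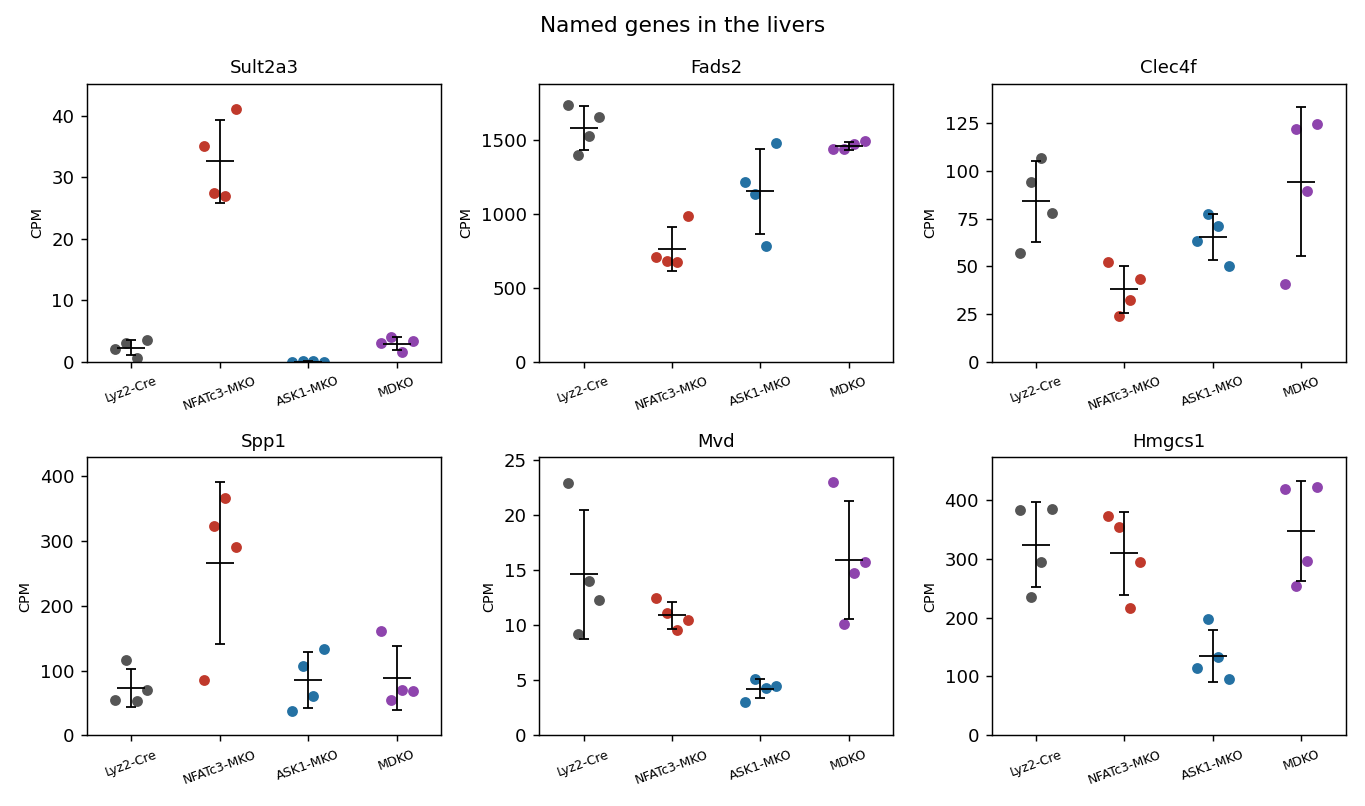
CPM of 6 genes in each liver, on linear axes from 0; points are livers, bars the group mean ± SD (n = 4). Sult2a3, Fads2, Clec4f and Spp1 were called changed in the livers labelled NFATc3-MKO, and Sult2a3, Mvd and Hmgcs1 in those labelled ASK1-MKO. None was called in the MDKO livers against Lyz2-Cre livers, though MDKO replicate 1 stood at 41.0 CPM for Clec4f, within the NFATc3-MKO range of 24.1 to 52.3.

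The livers labelled ASK1-MKO were compared with the same controls. Cholesterol synthesis genes were called lower as a list, as were targets of the oxidative stress regulator NRF2, glycolytic genes and red cell transcripts, of which fewer members passed. None of these calls held with an estimated correlation in camera (adjusted p = 0.654 to 0.76). Mvd, an enzyme of the mevalonate pathway, fell from 14.61 ± 5.89 to 4.24 ± 0.884 CPM (−1.79 ± 0.27, edgeR adjusted p = 0.000815), and Hmgcs1 from 323.8 ± 72.7 to 135 ± 44.2 CPM (−1.26 ± 0.24, 0.00443). The cytochrome P450 genes Cyp3a41a (−7.34 ± 1.11, edgeR adjusted p = 0.000998, and −6.22 without Lyz2-Cre replicate 2) and Cyp3a44 (−4.55 ± 0.44, 3.65e-05) fell strongly, as did Sult2a3, from 2.29 ± 1.26 to 0.0168 ± 0.0194 CPM (0.0001), which rose in the livers labelled NFATc3-MKO. By the rule for named genes Ppp1r3g, which promotes glycogen synthesis, rose most (3.38 ± 0.68, 0.00604). In all, 593 genes rose and 533 fell (1126 in total), with at least 2-fold changes in 117 and 187.

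Of 22 cholesterol synthesis genes 13 fell and none rose (18 and 1 adjusted over the list alone, camera adjusted p = 2.55e-09, adjusted p = 0.757 with an estimated correlation), also Mvk (−1.12 ± 0.20) and Dhcr7 (−0.96 ± 0.17). Of 21 NRF2 targets 5 fell (6 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.76 with an estimated correlation). Among them were Gsta2 (−1.16 ± 0.20), Hmox1, the inducible heme oxygenase (−1.22 ± 0.27, edgeR adjusted p = 0.011), and Nfe2l2, which encodes NRF2 itself (−0.49 ± 0.12, lost without ASK1-MKO replicate 1 or Lyz2-Cre replicate 4, edgeR adjusted p = 0.0619 and 0.0577). Without ASK1-MKO replicate 4 or Lyz2-Cre replicate 1 that list was not called (camera adjusted p = 0.0634 and 0.112). Of 17 glycolytic genes Pfkp fell (−1.10 ± 0.22, 4 genes adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.654 with an estimated correlation, camera adjusted p = 0.0636 without Lyz2-Cre replicate 1). Erythroid transcripts fell in 2 of 5 (4 adjusted over the list alone, camera adjusted p = 0.00266, adjusted p = 0.675 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells, fell by 1.07 ± 0.13 on the log2 scale (edgeR adjusted p = 0.000227). The other, the beta-globin gene Hbb-bs (−0.78, edgeR adjusted p = 0.0467), lost its call without any 1 library other than ASK1-MKO replicate 3 (0.0583 to 0.13), with no filter (0.0601) and with the GC and length correction (0.178). The 21 cell cycle genes were higher as a list with no member past the threshold, also when adjusted over the list alone (camera adjusted p = 0.0449, adjusted p = 0.967 with an estimated correlation, camera adjusted p = 0.21 and 0.0912 without ASK1-MKO replicates 3 and 4, and 0.112, 0.116 and 0.182 without Lyz2-Cre replicates 1, 3 and 4).

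Among the other genes that rose most were Cyp2c54 (2.31 ± 0.26, edgeR adjusted p = 0.000112), Smad9, a transcription factor of bone morphogenetic protein signalling (1.99 ± 0.32, 0.00127), Wsb1 (2.23 ± 0.38) and Slco1a1 (2.13 ± 0.47, 0.0106), which fell in the livers labelled NFATc3-MKO. The linker histone genes H1f3 (−3.90 ± 0.50) and H1f4 (−3.02 ± 0.44) and the phosphate transporter gene Slc34a2 (−4.42 ± 0.62) were among those that fell most. Without ASK1-MKO replicate 4, H1f3 stood at −4.77 and Slc34a2 at −5.35. Mup19 (2.51 ± 0.36), Cyp3a41a and Cyp3a44 have close paralogs that can share reads. The count of 1126 was 640 and 730 without ASK1-MKO replicates 1 and 2, and 587 and 632 without Lyz2-Cre replicates 3 and 4. The 2 groups did not overlap in 2428 genes (18.2%), against a chance share of 0.0286.

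Livers labelled MDKO, meant to show the loss of both proteins, did not differ detectably from Lyz2-Cre livers. No gene was called changed by edgeR, DESeq2 or voom, and 35 genes had an edgeR p under 0.05 before adjustment. For independent livers without differences 665 would be expected. Same-numbered livers of these 2 groups deviated together (correlations of 0.24 to 0.53 across genes), so the count that chance would give is not known. With the replicate number as a block, in the fit of all livers or of these 2 groups alone, the edgeR count was also 0. None of the lists was called with all libraries. With 1 library left out, 0 to 5 gene lists and 0 to 2 marker lists were called. The 5 genes with the smallest p, given as values, were Gm21244 (log2 change 0.70), Amy2a5 (3.09), Flywch2 (1.49), Gm21992 (1.29) and Eno1b (1.99), each at an edgeR adjusted p of 1. Genes moved in the single knockouts stayed near the control level here in the median, though these sets were chosen by their contrast with the same controls. The 502 genes that rose in livers labelled NFATc3-MKO had a median log2 change of 0.76 there and 0.02 in MDKO, and the 622 that fell −0.70 and −0.01. For ASK1-MKO the medians were 0.67 and 0.01 for the 593 that rose and −0.80 and −0.03 for the 533 that fell. Without MDKO replicate 3, the library of low depth, the count also stayed at 0. The 2 groups did not overlap in 61 genes (0.5%), where the chance share for independent livers is 0.0286.

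MDKO livers were also set directly against each single knockout. Same-numbered MDKO and Lyz2-Cre livers deviated together (correlations of 0.24 to 0.53 across genes), and whether they share handling or animals stays open. The comparisons below may therefore largely repeat those against Lyz2-Cre livers with the sign turned, and are not independent of them. Against NFATc3-MKO livers, 540 genes were higher and 438 lower, 978 in all. Slco1a1 (2.92 ± 0.52, edgeR adjusted p = 0.005, and 3.97 without NFATc3-MKO replicate 1), Cyp17a1 (2.43 ± 0.34, 0.00219), Fads2 (0.94 ± 0.17, 0.00504) and C6 (1.00 ± 0.15, 0.00262) were higher in MDKO. Sult2a3 (−3.41 ± 0.35, 0.000271), Ces4a (−2.42 ± 0.44) and Lox (−3.18 ± 0.67, 0.0102, and −2.45 without NFATc3-MKO replicate 2) were lower, Lox not with only the 2 groups in the fit (0.0504). Fibrosis genes were lower in 6 of 30 (20 adjusted over the list alone, camera adjusted p = 6.27e-05, adjusted p = 0.863 with an estimated correlation), and lipogenesis genes higher in 5 and lower in 1 of 18 (9 and 1 adjusted over the list alone, 6.27e-05, adjusted p = 0.729 with an estimated correlation). Of the markers, Kupffer cell genes were higher (3, 6 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.813 with an estimated correlation). Those of lipid-associated macrophages (2, 12 adjusted over the list alone, camera adjusted p = 0.000511, adjusted p = 0.863 with an estimated correlation) and of neutrophils (3, 5 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.729 with an estimated correlation) were lower. Hepatocyte markers were higher with 1 gene past the threshold, also adjusted over the list alone (camera adjusted p = 0.000511, adjusted p = 0.729 with an estimated correlation). The other lists called here lost their call without at least 1 library. Genes of fatty acid oxidation were higher with none past the threshold, also adjusted over the list alone (camera adjusted p = 0.00302, adjusted p = 0.936 with an estimated correlation, camera adjusted p = 0.0523 without MDKO replicate 1 and 0.0526 without NFATc3-MKO replicate 2). Bile acid genes were higher in 2 (5 adjusted over the list alone, camera adjusted p = 0.0208, adjusted p = 0.863 with an estimated correlation, camera adjusted p = 0.112 and 0.124 without NFATc3-MKO replicates 2 and 3). Endothelial markers were higher in 1 (3 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.863 with an estimated correlation, camera adjusted p = 0.0967 and 0.0502 without NFATc3-MKO replicates 2 and 3). Cholangiocyte markers were lower with none past the threshold (3 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.863 with an estimated correlation, camera adjusted p = 0.089 without MDKO replicate 2 and 0.061, 0.0839 and 0.0726 without NFATc3-MKO replicates 2, 3 and 4). Apoptosis genes were lower in 1 (none adjusted over the list alone, camera adjusted p = 0.0351, adjusted p = 0.729 with an estimated correlation, camera adjusted p = 0.0757 and 0.0791 without MDKO replicates 1 and 3, 0.114 and 0.0502 without NFATc3-MKO replicates 2 and 3).

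The count of 978 was 335 and 346 without MDKO replicates 3 and 4, 567 without NFATc3-MKO replicate 3 and 283 with only the 2 groups in the fit, and 1694 genes (12.7%) did not overlap, against a chance share of 0.0286.

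Against ASK1-MKO livers, 461 genes were higher in MDKO and 567 lower, 1028 in all. Cyp3a41a (7.45 ± 1.11, edgeR adjusted p = 0.000947, and 5.81 without MDKO replicate 2), Sult2a3 (2.94 ± 1.04 against 0.0168 ± 0.0194 CPM, 4.17e-05), Mvd (1.91 ± 0.27, 0.000507) and Alas2 (0.96 ± 0.14, 0.000453) were higher, and Mup19 (−2.61 ± 0.36, 0.000453) was lower. Cholesterol synthesis genes were higher in 14 of 22 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.83e-11, adjusted p = 0.669 with an estimated correlation). Genes of the unfolded protein and integrated stress response were lower in 5 of them (9 adjusted over the list alone, camera adjusted p = 0.0448, adjusted p = 0.982 with an estimated correlation), including Hsp90b1, a chaperone of the endoplasmic reticulum (−0.62 ± 0.13, edgeR adjusted p = 0.00632). That list lost its call without ASK1-MKO replicate 1 (camera adjusted p = 0.0603) or 3 (0.429) and without MDKO replicate 1 (0.153) or 4 (0.106). Cell cycle genes were lower in 1, also adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.982 with an estimated correlation, camera adjusted p = 0.098 without ASK1-MKO replicate 3 and 0.106 without MDKO replicate 4). NRF2 targets were higher in 5, also adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.669 with an estimated correlation, camera adjusted p = 0.0581 without MDKO replicate 1). Glycolytic genes were higher in 1 (5 adjusted over the list alone, camera adjusted p = 0.0448, adjusted p = 0.669 with an estimated correlation, camera adjusted p = 0.114 and 0.0744 without ASK1-MKO replicates 2 and 3, 0.138 without MDKO replicate 1). Erythroid transcripts were higher in 1 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.669 with an estimated correlation).

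Map3k5 was lower in MDKO than in ASK1-MKO livers (−0.60 ± 0.15, edgeR adjusted p = 0.0252, 0.0856 without ASK1-MKO replicate 2, 0.065, 0.0732 and 0.0536 without MDKO replicates 1, 3 and 4). The count of 1028 was 547 and 684 without ASK1-MKO replicates 1 and 2 and 563 without either MDKO replicate 3 or 4, and 2405 genes (18.1%) did not overlap, against a chance share of 0.0286.

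The interaction asks whether losing both proteins equals the sum of the single losses. It was past the threshold in 2153 genes, positive in 1088 and negative in 1065. Lyz2-Cre and MDKO livers enter it with the same sign, and their same-numbered livers deviated together. The fit takes all livers as independent, so the SEs and p values of the interaction may be too small. As MDKO livers stood near the controls, it also largely mirrors the summed single-label changes with the sign turned. A positive value means that MDKO livers stood above the sum of the changes seen with the single labels. Positive were Slc34a2 (6.29 ± 0.79, edgeR adjusted p = 0.000139), H1f3 (5.77 ± 0.66, 8.94e-05), Mvd (2.33 ± 0.37, 0.000661), Fads1 (1.15 ± 0.18) and Fads2 (1.39 ± 0.24). Negative were Ppp1r3g (−4.24 ± 0.94, 0.00624), Rfx4 (−3.32 ± 0.67) and Mlxipl, which encodes the carbohydrate-responsive factor ChREBP (−1.51 ± 0.21, 0.000246). Slc34a2 and H1f3 were 7.22 and 6.63 without ASK1-MKO replicate 4, Rfx4 −3.93 without Lyz2-Cre replicate 1 and Ppp1r3g −3.34 without NFATc3-MKO replicate 4. Among the lists, cholesterol synthesis had 10 positive and 1 negative of 22 (15 and 1 adjusted over the list alone, camera adjusted p = 9.32e-06, adjusted p = 0.906 with an estimated correlation). Kupffer cell markers had 3 positive of 10 (8 adjusted over the list alone, 0.0144, adjusted p = 0.906 with an estimated correlation, camera adjusted p = 0.056 without NFATc3-MKO replicate 2). Fibrosis genes had 2 negative (1 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.906 with an estimated correlation, camera adjusted p = 0.0632 without Lyz2-Cre replicate 1, 0.123 and 0.0638 without NFATc3-MKO replicates 2 and 4). Lipogenesis had 6 positive and 2 negative, also adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.906 with an estimated correlation, camera adjusted p = 0.123 and 0.0566 without NFATc3-MKO replicates 2 and 3). Oxidative phosphorylation (camera adjusted p = 0.0357), hepatocyte markers (0.0357) and endothelial markers (0.0398, 0.069 with the replicate block) were positive, each with an adjusted p = 0.906 with an estimated correlation. Each of these 3 calls was lost without Lyz2-Cre replicate 1 (camera adjusted p = 0.176, 0.0653 and 0.0653) or NFATc3-MKO replicate 2 (0.237, 0.167 and 0.123), among other libraries. Without any 1 library the count stayed between 1512 and 2291.

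The changes in livers labelled NFATc3-MKO and ASK1-MKO were then compared with each other. They overlapped in direction: 138 genes rose in both (22.4 expected for independent sets) and 137 fell in both (24.9 expected). Only 14 rose with NFATc3-MKO and fell with ASK1-MKO (20.1 expected), and 6 did the reverse (27.7 expected). Both comparisons use the same Lyz2-Cre livers, which alone gave a correlation across genes of 0.49 to 0.54 in simulated unchanged groups. In 10 simulations of such groups 0 called genes were shared, but without real changes few genes can be called, so this does not show how many the common controls add where groups differ. The observed Pearson r was 0.25, below that range, with a covariance of 0.0493 against 0.036 in the simulations, and r ran from −0.04 to 0.26 with the controls split. Genes are not independent replicates, so no p is given.

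Cultures labelled NFATc3-MKI were compared with their controls to find what added NFATc3 does in macrophages. Genes of inflammation and of the interferon response were higher, those of cholesterol and fatty acid synthesis and of the circadian clock were lower, and lipid storage genes were higher, each called as a list. None of these list calls held with an estimated correlation in camera (adjusted p = 0.159 for each). Il1rn, which encodes the interleukin-1 receptor antagonist, rose from 20.3 ± 3.03 to 164 ± 25.6 CPM (log2 change 3.01 ± 0.13, edgeR adjusted p = 1.1e-13), and the chemokine gene Ccl2 from 0.496 ± 0.231 to 15.5 ± 1.88 CPM (4.95 ± 0.30, 1.18e-11). Insig1, a brake on sterol synthesis that is itself induced by low sterol, fell from 419 ± 10.8 to 132 ± 10.1 CPM (−1.66 ± 0.09, 9.17e-13). In all, 2203 genes rose and 2249 fell of 13363 (4452 in total), with at least 2-fold changes in 361 and 230.

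Of 18 inflammatory cytokine and chemokine genes 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 6.46e-12, adjusted p = 0.159 with an estimated correlation), also Ptgs2, the inducible cyclooxygenase (1.63 ± 0.10). Of 24 interferon response genes 20 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 8.37e-12, adjusted p = 0.159 with an estimated correlation), with Rsad2 at 2.14 ± 0.12 and Zbp1 at 2.28 ± 0.18. Of 18 genes of NF-kB and Toll-like receptor signalling 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00593, adjusted p = 0.211 with an estimated correlation), with the lipopolysaccharide co-receptor gene Cd14 at 1.32 ± 0.09. Of 17 genes of the unfolded protein and integrated stress response 10 rose, as many as adjusted over the list alone (camera adjusted p = 0.000367, adjusted p = 0.211 with an estimated correlation), including Ddit3 (1.25 ± 0.09) and Asns (0.95 ± 0.09). Cholesterol synthesis fell in 19 of 21 genes (19 adjusted over the list alone, camera adjusted p = 6.46e-12, adjusted p = 0.159 with an estimated correlation), with Hmgcs1 at −1.15 ± 0.09. Lipogenesis fell in 11 of 15 (11 adjusted over the list alone, camera adjusted p = 0.000561, adjusted p = 0.159 with an estimated correlation), with Scd1 at −1.02 ± 0.09 and Fasn, the fatty acid synthase gene, at −0.61 ± 0.10. Of 10 lipid droplet and fatty acid uptake genes 6 rose, also adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.159 with an estimated correlation), with Plin2, which coats lipid droplets, at 1.65 ± 0.10 and Fabp4 at 3.63 ± 0.15 (edgeR adjusted p = 2.07e-14). Clock genes fell in 10 of 13, also adjusted over the list alone (camera adjusted p = 3.57e-05, adjusted p = 0.159 with an estimated correlation), with Per3 at −1.36 ± 0.20 and Nr1d2 at −0.66 ± 0.10.

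Macrophage markers rose too: 6 of 9 pan-macrophage genes (6 adjusted over the list alone, camera adjusted p = 0.000958, adjusted p = 0.159 with an estimated correlation), with the Fc receptor gene Fcgr1 at 1.40 ± 0.11, and 5 of 8 markers of lipid-associated macrophages (5 adjusted over the list alone, camera adjusted p = 0.00593, adjusted p = 0.159 with an estimated correlation), with Spp1 at 2.17 ± 0.11. Of 16 phagocytic and scavenger receptor genes 7 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0425, adjusted p = 0.266 with an estimated correlation, camera adjusted p = 0.0697 with the replicate block), with the scavenger receptor genes Msr1 at 2.08 ± 0.11 and Cd36 at 2.51 ± 0.28. That list lost its call without control replicate 1 (camera adjusted p = 0.0831), control replicate 3 (0.052) or NFATc3-MKI replicate 1 (0.0856). Lysosome genes rose in 6 and fell in 2 of 16 (8 and 3 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.336 with an estimated correlation), a call lost with the replicate block (camera adjusted p = 0.0536) and without control replicate 3 (0.052) or NFATc3-MKI replicate 1 (0.0733). Apoptosis genes rose in 9 and fell in 3 of 20 (10 and 3 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.162 with an estimated correlation, camera adjusted p = 0.0632 without control replicate 3 and 0.0733 without NFATc3-MKI replicate 1). Glycolytic genes fell in 5 of 17, also adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.441 with an estimated correlation, camera adjusted p = 0.128 without NFATc3-MKI replicate 2). Short lists of alternative activation (3 of 7 rose, camera adjusted p = 0.00698), matrix genes (4 of 5, 0.00277) and endothelial markers (2 of 4, 0.00612) were higher, with the same counts adjusted over the list alone and an adjusted p = 0.159 with an estimated correlation.

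Among the largest changes were Ifi209 (4.46 ± 0.28), Edn1, the endothelin-1 gene, at 3.85 ± 0.983 against 0.078 ± 0.0676 CPM (edgeR adjusted p = 2.39e-07), and Ly6c1, at 2.60 ± 0.772 against 0.0444 ± 0.0769 CPM (3.65e-06). Iigp1, which encodes an interferon-induced GTPase, and the chemokine gene Ccl7 had no counts in the controls and were at least 12.2-fold and 11.5-fold higher. Of the genes that fell most, Ranbp3l (−2.37 ± 0.16), Mxd4, a repressor of MYC targets (−1.87 ± 0.14), and Hyal1, a hyaluronidase gene (−1.79 ± 0.13), had adjusted p values from 5.4e-11 to 6.93e-10 (edgeR). The 2 groups did not overlap in 6120 genes (45.8%), against a chance share of 0.1. Without any 1 library the count stayed between 3272 and 4824. These cells differed from the other culture set in basic macrophage markers: Adgre1, which encodes F4/80 and was named after its values were seen, stood at 33.62 ± 1.12 CPM in these controls and 2714 ± 22.6 in the ASK1-MKI controls, over the genes of both tables.

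Cultures labelled ASK1-MKI were compared with their own controls to find what added ASK1 does. Proliferation genes, neutrophil and progenitor genes and glycolytic genes were called lower as lists, and macrophage markers, interferon response genes and antigen presentation genes higher. With an estimated correlation in camera the call of the proliferation list held (adjusted p = 0.0346) and those of the other lists did not (adjusted p = 0.0941 to 0.159). Mki67, a marker of dividing cells, fell from 189 ± 3.72 to 22 ± 0.636 CPM (−3.11 ± 0.04, edgeR adjusted p = 4.07e-101), the collagenase gene Mmp8 from 999 ± 25.6 to 132 ± 3.89 CPM (−2.92 ± 0.03, 1.13e-124), and the neutrophil chemokine gene Cxcl2 from 100 ± 6.06 to 2.41 ± 0.356 CPM (−5.37 ± 0.08, 1.43e-94). The 4 Y chromosome genes followed were not detected in the ASK1-MKI libraries: Ddx3y, Eif2s3y, Uty and Kdm5d had no counts there and 96.3, 67.1, 37.8 and 34.7 CPM in the controls, so they were at least 1600-, 1120-, 630- and 578-fold lower. If the donors differed in sex, sex and genotype would coincide in this comparison. In all, 2794 genes rose and 2792 fell of 11380 (5586 in total), with at least 2-fold changes in 129 and 557. Replicates of this set were very alike (common biological coefficient of variation 0.021). If they are repeats of 1 culture, which stays open, these p values do not cover the spread between cultures.

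Of 21 cell cycle genes 20 fell (21 adjusted over the list alone, camera adjusted p = 1.18e-13), and this list alone kept its call with an estimated correlation (adjusted p = 0.0346 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell by 3.06 ± 0.06 on the log2 scale. Glycolysis fell in 15 of 17 genes (16 adjusted over the list alone, camera adjusted p = 3.83e-08, adjusted p = 0.0941 with an estimated correlation), with the lactate exporter gene Slc16a3 at −1.25 ± 0.04 and the glucose transporter gene Slc2a1 at −0.93 ± 0.04. Oxidative phosphorylation genes of the nucleus rose in 12 of 22 and fell in 1, the count adjusted over the list alone being the same (camera adjusted p = 0.0194, adjusted p = 0.283 with an estimated correlation), with Cycs at 0.27 ± 0.03, whereas 8 of 12 mitochondrially encoded RNAs fell, as many as adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.283 with an estimated correlation), with mt-Cytb at −0.56 ± 0.02. Acute phase genes fell in 7 of 7, also adjusted over the list alone (camera adjusted p = 9.84e-06, adjusted p = 0.14 with an estimated correlation), with Lcn2 at −1.26 ± 0.02. Of 18 NF-kB and Toll-like receptor genes 11 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation), with Cd14 at −1.73 ± 0.03. Of 12 immediate early genes 8 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0209, adjusted p = 0.159 with an estimated correlation).

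Interferon response genes rose in 19 of 25 and fell in 2, also adjusted over the list alone (camera adjusted p = 9.84e-06, adjusted p = 0.14 with an estimated correlation). Irf7 rose (0.76 ± 0.02) and Ifit2 fell (−0.78 ± 0.02), although both are interferon-induced. MHC class II genes rose in 4 of 7 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.159 with an estimated correlation), with Cd74 at 1.15 ± 0.05 and H2-Aa at 1.17 ± 0.06. Lysosome genes rose in 11 of 17 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.258 with an estimated correlation), with Atp6v0d2, a proton pump subunit, at 1.63 ± 0.03. Phagocytic and scavenger receptor genes rose in 11 of 18 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.0193, adjusted p = 0.159 with an estimated correlation), with Mfge8 at 1.58 ± 0.03 and Marco at −1.59 ± 0.02. Pan-macrophage markers rose in 10 of 12 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.000182, adjusted p = 0.103 with an estimated correlation), with Aif1 at 0.68 ± 0.03. Neutrophil markers fell in 6 of 7 (camera adjusted p = 0.000348, adjusted p = 0.159 with an estimated correlation), Kupffer cell markers in 6 of 7 (0.00496, adjusted p = 0.14 with an estimated correlation) and myeloid progenitor markers in 6 of 6 (0.000684, adjusted p = 0.125 with an estimated correlation), the same counts as adjusted over the list alone. Mmp9 fell by 5.21 ± 0.17 and Mpo, the myeloperoxidase gene, by 5.44 ± 0.30 on the log2 scale, 6.78 without ASK1-MKI replicate 1. The genes that rose most, among them Serping1 (3.92 ± 0.46), Col4a1 (3.25 ± 0.25) and Serpinh1 (2.98 ± 0.36), stood at 1.78, 5 and 2.25 CPM, and Cxcl9, an interferon-induced chemokine gene, at 25.1 CPM (2.42 ± 0.10). The 2 groups did not overlap in 6204 genes (54.5%), against a chance share of 0.1. With autosomal genes only, chosen after seeing the data, 5402 genes were changed.

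**Figure D4:**
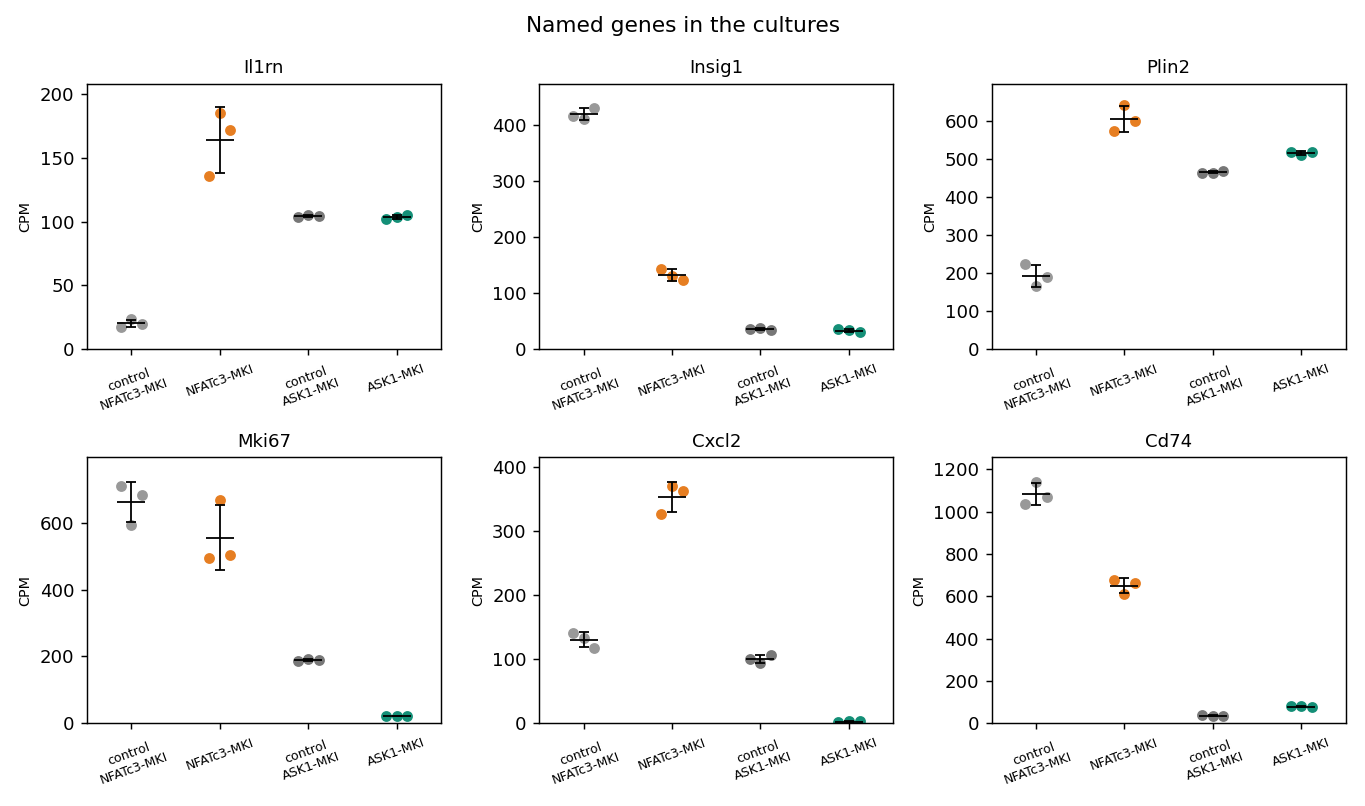
CPM of 6 genes in each culture, on linear axes from 0; points are cultures, bars the group mean ± SD (n = 3). Il1rn, Insig1 and Plin2 differ between NFATc3-MKI cells and their controls; Mki67, Cxcl2 and Cd74 differ between ASK1-MKI cells and theirs.

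The responses of the 2 knock-in cultures, each against its own controls, were compared over the 10064 genes tested in both. The sets overlapped more than independent sets would: 821 genes rose in both (474 expected) and 760 fell in both (431 expected), with 306 (457 expected) and 242 (448 expected) in opposite directions. Across genes, Pearson's r of the log2 changes was 0.115 and Spearman's rho 0.267; genes are not independent replicates.

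Genes moved by the knock-ins were then tested in the livers, to see whether they move the other way where the same protein is lost. In livers labelled ASK1-MKO all 4 sets were called and moved opposite to the cultures: genes that rose with NFATc3-MKI were lower (camera adjusted p = 0.0187), those that fell were higher (1.64e-05), those that rose with ASK1-MKI were lower (0.0118) and those that fell were higher (0.00381). No call held with an estimated correlation (adjusted p = 0.238, 0.233, 0.173 and 0.233 with an estimated correlation), and the median changes were small, from −0.10 to 0.13 on the log2 scale. With 1 library left out, 2 to 4 of the sets were called in ASK1-MKO livers. None of the 4 sets was called in livers labelled NFATc3-MKO or MDKO by camera. Log2 changes in ASK1-MKO livers also tracked GC content and gene length across genes (Spearman's rho −0.188 and 0.173). In NFATc3-MKO livers these were 0.05 and −0.108, and in MDKO livers −0.046 and 0.037. The sets were not tested with that trend removed, so its part in these calls is not known. With the 50 genes of smallest p per direction 1 set was called in ASK1-MKO livers, and the genes that fell with ASK1-MKI turned lower (camera adjusted p = 0.725).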

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

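The GC and length correction was chosen after seeing the data but before its result was seen. The tests of harvest time, shared handling, shared animals, annotation, sex-linked genes and repeats of 1 culture were chosen only after the results were seen, and the other tests before.

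Lyz2-Cre and MDKO livers were alike while both single knockouts lay apart from them. A trend on GC content and gene length is argued against as the whole cause, since 1616 genes in NFATc3-MKO and 1348 in ASK1-MKO livers were changed once it was removed. A harvest at another time of day is a candidate explanation: the clock genes' median absolute log2 change was 0.58 in NFATc3-MKO and 1.02 in ASK1-MKO livers, at percentile 100 of 10000 random lists in both, where such lists had medians of 0.22 and 0.21. Joint handling of Lyz2-Cre and MDKO livers stays open, since same-numbered libraries deviated together (lowest correlation 0.24) but handling and group coincide, and so do libraries of the same animals: the same-numbered chi-squares per degree of freedom were 13.65, 8.97, 2.31 and 7.62, against 1.59 to 1.99 and 2.82 to 8.94 between replicates of the 2 culture sets and at least 11.1 between livers of 1 group. Such chi-squares grow with depth, which differed between these sets. The 2.31 and the 11.1 both involve MDKO replicate 3, at 8912117 counts. Loss of both proteins cancelling the single effects is the biological explanation that the design names, and it was not tested apart from the explanations above.

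The cells of the NFATc3-MKI set differed from those of the ASK1-MKI set in macrophage identity. A difference in annotation or depth is argued against, because the pan-macrophage markers had a median log2 ratio of −5.94 over the 21957 genes of both tables, where the cell cycle genes had 2.41. A macrophage line that lacks Pycard in place of primary cells is a candidate explanation: Pycard was at most 0.25 CPM in these 6 libraries and 18.9 in the ASK1-MKI controls. The labels call these cells primary, and other culture conditions were not tested.

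About as many genes differed between ASK1-MKI and control cells as did not. Sex-linked genes are argued against as the whole of it, since 49.1% of autosomal genes were changed. Donors of different sex stay open. The 4 Y chromosome genes followed had no counts in ASK1-MKI cells and 34.7 to 96.3 CPM in the controls, as donors of different sex would give. Xist, also on the fixed list of sex-linked genes, is not among the genes given for this set, so it could not be examined. Of 4 genes that escape X inactivation 3 were higher, Kdm6a (0.53), Kdm5c (0.18) and Eif2s3x (0.31), but Ddx3x was lower (−0.23), and sex would coincide with genotype. Repeats of 1 culture in place of separate cultures could also make small differences pass, and stay open because separate cultures may be as alike as these (highest chi-square per degree of freedom 1.99). An effect of added ASK1 is the explanation the design names, and it cannot be told apart from donor sex.

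Other splits of the same libraries were fitted as well. In NFATc3-MKO against Lyz2-Cre, chance cannot be excluded: 2 of 35 splits gave as many changed genes as the real 1124, the highest other giving 1135. That split set NFATc3-MKO replicates 2, 3 and 4 with Lyz2-Cre replicate 2 against the rest, a structure in which NFATc3-MKO replicate 1 lies apart from its group. The share of splits with as many changed genes was under 0.05 for ASK1-MKO against Lyz2-Cre (1 of 35, 1126, highest other 0), for MDKO against NFATc3-MKO (1 of 35, 978, highest other 593) and for MDKO against ASK1-MKO (1 of 35, 1028, highest other 0). Chance is argued against there only weakly, since 1 of 35 is the smallest possible share and was not adjusted over the comparisons. For the interaction 1 of 100 regroupings gave as many (2153, highest other 374), but they regroup all 16 livers freely and keep neither the likeness of same-numbered Lyz2-Cre and MDKO livers nor the effects of the single labels, so chance is argued against only for such regroupings. For MDKO against Lyz2-Cre 35 of 35 splits gave as many as the real 0, the highest other giving 3. For NFATc3-MKI (4452) and ASK1-MKI (5586), with the highest other at 0, 10 splits are too few for a share under 0.05.

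Of 165 groups of 4 values tested for a library far from the others, 15 had one, where about 8.2 are expected by chance. Total counts in MDKO replicate 3 were 8910000, against 23100000 to 24700000 in the other MDKO livers. Nfatc3 stood at 19.6 CPM in NFATc3-MKO replicate 3, against 30.9 to 31.5 in the others of its group. In NFATc3-MKO replicate 1, Slco1a1 stood at 5.7 CPM (others 0.87 to 1.32), C6 at 19.4 (14 to 14.7) and Txnip, a gene named after its values were seen, at 325 (158 to 176). In NFATc3-MKO replicate 4, Hspa1b stood at 17.7 CPM (6.76 to 8.25) and Fads2 at 985 (670 to 704). In Lyz2-Cre replicate 2, Lox stood at 1.66 CPM (0.374 to 0.516), S100a9 at 4.16 (0.982 to 1.5), S100a8 at 3.74 (0.421 to 0.885), Epcam at 3.87 (2.68 to 2.71) and Cyp3a41a at 136 (20.5 to 26.9). Zfp454 stood at 1.97 CPM in Lyz2-Cre replicate 1 (0.722 to 0.935), Ppp1r3g at 5 in Lyz2-Cre replicate 4 (1.4 to 2.01) and Alas2 at 12.3 in ASK1-MKO replicate 2 (16.1 to 16.3). The interaction test was past the threshold in 2153 genes. Its p values may be too small, because same-numbered Lyz2-Cre and MDKO livers deviated together and the fit takes all livers as independent.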

How the results depend on the processing

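The fit of MDKO and Lyz2-Cre livers with the block, the GC and length correction and the autosomal genes of ASK1-MKI were chosen after seeing the data. No named gene reversed under any alternative while past the threshold in the main fit or in the alternative. Of the values, 2273 kept their side of the threshold, 98 newly passed it and 73 no longer did. With a library left out the numbers were 2360, 51 and 277. Values past the threshold in neither fit could change sign, as Map3k5 did in NFATc3-MKO (−0.19 to 0.12 with a library left out). The alternative on a pseudocount had no value for count data and was not run. As a limit of depth and spread, in simulations of the liver design 22% of genes changed 1.5-fold were recovered.

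With an added 2-fold limit 277 genes were changed in NFATc3-MKO, 304 in ASK1-MKO, 231 in MDKO against NFATc3-MKO, 279 in MDKO against ASK1-MKO, 1006 in the interaction, 591 in NFATc3-MKI and 686 in ASK1-MKI, the limit itself lowering the counts. At an adjusted p under 0.1 they were 2088, 1845, 2006 and 1706 in the first 4. The DESeq2 Wald test gave 1719 in NFATc3-MKO and 1628 in MDKO against NFATc3-MKO, and voom with quality weights 2613, 2621, 2636 and 2553 in those 4 and 3714 in the interaction. Only the 2 groups compared gave 218 and 283 in NFATc3-MKO and MDKO against NFATc3-MKO, but 1470 and 1257 in ASK1-MKO and MDKO against ASK1-MKO, and the GC correction 1476 in MDKO against NFATc3-MKO. Apart from the construction of these alternatives, the cause was not tested.

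Nfatc3 passed in NFATc3-MKO with voom (−0.31, limma adjusted p = 0.0419) and the GC correction (−0.32, edgeR adjusted p = 0.0313), over a range of 0.0313 to 0.295. In MDKO against NFATc3-MKO it did so with voom (0.34, limma adjusted p = 0.0268) and the GC correction (0.33, edgeR adjusted p = 0.0308). Map3k5 passed in the interaction with DESeq2 (−0.63, adjusted p = 0.0441), voom (−0.52, limma adjusted p = 0.0197) and the GC correction (−0.63, edgeR adjusted p = 0.0427). With DESeq2 Nfatc3 no longer passed in NFATc3-MKI (−0.27, adjusted p = 0.0523, range 0.00319 to 0.166), nor Map3k5 in ASK1-MKI (−0.16, adjusted p = 0.0827, range 0.0228 to 0.0827). The cause was not tested.

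With an estimated correlation 0 gene lists and 0 marker lists were called in each comparison, except 1 gene list in ASK1-MKI, and 0 of 4 knock-in sets in ASK1-MKO livers. With the 50 genes of smallest p per direction 1 set was called there, and the genes that fell with ASK1-MKI were reversed (camera adjusted p = 0.725). With the replicate block 2 marker lists were called in MDKO against ASK1-MKO, pan-macrophage markers being added (camera adjusted p = 0.0376). It ended the calls of Hspa1b (edgeR adjusted p = 0.053) and Cd163 (0.0776) in NFATc3-MKO and of Hspa1b (0.0506) and Spp1 (0.0921) in MDKO against NFATc3-MKO, and among the genes and lists followed it ended no other call apart from those of the lists given with it in the results. Over all genes the calls shared with the block were 1094 of 1124 in NFATc3-MKO, 1105 of 1126 in ASK1-MKO, 953 of 978 in MDKO against NFATc3-MKO, 1014 of 1028 in MDKO against ASK1-MKO, 2094 of 2153 in the interaction, 4218 of 4452 in NFATc3-MKI and 5468 of 5586 in ASK1-MKI. With the controls split the lowest correlations of changes were −0.04 for NFATc3-MKO with ASK1-MKO, −0.34 for NFATc3-MKO with MDKO and −0.19 for ASK1-MKO with MDKO, whose highest was −0.03. The cause was not tested.

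With each library left out, changed genes ranged from 268 to 1585 in NFATc3-MKO, 587 to 1025 in ASK1-MKO, 335 to 1423 in MDKO against NFATc3-MKO and 547 to 833 in MDKO against ASK1-MKO. Map3k5 ranged from 0.51 to 0.63 in ASK1-MKO, −0.64 to −0.51 in MDKO against ASK1-MKO, −0.72 to −0.42 in the interaction and −0.17 to −0.16 in ASK1-MKI. Nfatc3 ranged from −0.35 to −0.21 in NFATc3-MKI and 0.05 to 0.11 in ASK1-MKI. Gene lists called ranged from 2 to 9 in NFATc3-MKO, 1 to 6 in ASK1-MKO, 0 to 5 in MDKO against Lyz2-Cre, 2 to 10 in MDKO against NFATc3-MKO, 2 to 6 in MDKO against ASK1-MKO and 1 to 6 in the interaction. Marker lists called ranged from 0 to 2 in MDKO against Lyz2-Cre, 1 to 3 in MDKO against ASK1-MKO and 0 to 4 in the interaction. Knock-in sets called ranged from 2 to 4 in ASK1-MKO and 0 to 1 in MDKO. In MDKO against Lyz2-Cre, oxidative phosphorylation ranged over camera adjusted p values of 0.000916 to 0.99 and cell cycle over 0.000706 to 0.751. Their direction reversed without Lyz2-Cre replicate 1 (0.0439) and without Lyz2-Cre replicate 2 (0.0377).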

Other observations

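The clock genes below and the genes Rcan1 and Txnip were followed after their values were seen, and the tests of sex-biased genes were chosen before theirs were. Of 15 clock genes 3 rose and 2 fell in NFATc3-MKO and 7 rose and 3 fell in ASK1-MKO, and the list was called in neither (camera adjusted p = 0.259 and 0.0949). Nr1d1, a repressor of the clock, rose in livers labelled NFATc3-MKO (log2 change 1.53, edgeR adjusted p = 0.00704) and ASK1-MKO (1.78, 0.00161), and Cry1 fell in both (−1.08, 0.00321 and −1.02, 0.00186). Per2 fell in both (−0.58, 0.0185 and −0.70, 0.00489), and Nr1d2 rose in both (0.80, 0.011 and 1.51, 0.000117). In NFATc3-MKO the calls of Per2 (0.078 and 0.0641 without Lyz2-Cre replicates 3 and 4, 0.0594 with only the 2 groups) and Nr1d2 (0.0528 without Lyz2-Cre replicate 3, 0.0554 with only the 2 groups) were not stable by edgeR adjusted p. Bmal1 stood at −1.86 in ASK1-MKO (edgeR adjusted p = 0.0383), a call lost without Lyz2-Cre replicate 3 (0.17) or 4 (0.0668), without any ASK1-MKO replicate (0.0685 to 0.0971) and with no filter (0.0521), and at −1.64 (0.06) in NFATc3-MKO. In MDKO livers Nr1d1 stood at 0.06, Cry1 at −0.02 and Bmal1 at −0.10, each at an edgeR adjusted p of 1.

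Rcan1, a calcineurin regulator that NFAT proteins induce, fell in livers labelled NFATc3-MKO, from 60.6 to 20.2 CPM (−1.58, edgeR adjusted p = 0.00235), and in those labelled ASK1-MKO (−1.02, 0.00915). Txnip, which binds thioredoxin, rose in both (1.21, 0.0196 and 1.47, 0.00531). In NFATc3-MKO its call was lost without Lyz2-Cre replicate 1 (edgeR adjusted p = 0.0543), 3 (0.0578) or 4 (0.0595). Rcan1 belongs to the fixed list of NFAT and calcineurin genes, and Txnip to that of ASK1 and stress MAP kinases. Picked after their values were seen, they do not speak for those lists or for a loss of the targeted proteins.

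Sult2a3, Slco1a1 and Cyp3a41a are known to differ between male and female livers, so it was tested whether other sex-biased genes moved apart in the single knockouts. They did not move as proposed in NFATc3-MKO livers, where male-biased genes were to fall and female-biased to rise: the median of the 10 male-biased genes lay 0.74 above that of the 7 female-biased genes. In ASK1-MKO livers, with the opposite proposal, the difference of 0.7 leaves it open, because female-biased genes had a median of −0.73 (camera adjusted p = 0.0527, adjusted p = 0.447 with an estimated correlation) and male-biased genes one of −0.03 (0.693).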
